A study of uncultured soil microorganism with 16 samples.

How the data were processed

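Functional genes were measured in genomic DNA of mangrove sediment with a GeoChip microarray, in 16 samples: 4 each from control plots, plots with nitrogen addition, warmed plots, and plots with both. Per the labels' protocols, each replicate was a plot, from which 2 cores were mixed, DNA was extracted from the sediment by freeze-grinding, and it was labelled with Cy5 by random priming before hybridisation. The values deposited by the authors are intensity on a linear scale, between 173.7 and 259068. They had been scaled by the authors by a method that is not given in the sources used here, as are the scanner and the rule by which a probe was listed as detected. A blank stood for a probe not listed as detected in that sample and was counted as 0 in sums. The deposited values covered 72416 probes, of which 20660 were listed in no sample, 34861 in all 16 and 0 in exactly 1. Between 39256 and 49136 probes were listed per sample, the summed intensity differed by 12.9% between the lowest and highest sample, and the lowest listed value by 44.6%. The number of arrays limits the precision.

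A gene family was the set of probes that share a gene name in the table. For each sample the intensities of a family's listed probes were summed, and log2 of the sum plus 225.7 (the 1st percentile of listed values) was used. Of 1085 families, the 944 listed in at least 4 of the samples were tested. Of these, 555 had at least 5 detected probes in some sample and 389 had fewer; 127 had a single probe. A linear model of the 4 group means was fitted by least squares and moderated with limma 3.58.1 in R 4.3.3, with data.table version 1.17.8 to read the values, and its two-sided p was adjusted by Benjamini-Hochberg within each contrast. The 6 contrasts were nitrogen, warming, and both treatments, each against control, the main effects of nitrogen and of warming, and their interaction. An adjusted p under 0.05 was called. Single probes were fitted the same way on log2 intensity, for the 39102 probes listed in at least 3 of 4 samples of every group, with blanks left as missing.

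The number of listed probes, the summed intensity and the lowest listed value were compared by two-sided exact permutation tests over 70 arrangements of 4 against 4 samples, where the smallest possible p is 0.0286. Main effects used 4900 arrangements within levels of the other factor, and the interaction 100000 random permutations; p was adjusted over the 6 contrasts. Composition was tested with Bray-Curtis dissimilarity over all probes by permutational multivariate analysis with the same arrangements, and drawn as principal coordinates. Lineage groups were the 38 phyla, classes or domains with at least 20 probes, from the lineage given in the table (351 probes had none).

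Of 29 gene lists, fixed by gene name, the 25 with at least 3 tested families were tested with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation. Nitrogen fixation (1 family), ammonification (2), anammox (2) and methane oxidation (2) had too few. Names that only share a prefix with a listed gene were kept out of the lists, such as vanA from the vancomycin resistance genes and the beta-carotene genes from betA. The families named in the text are, per contrast, up to 5 of the largest rises and falls past the threshold among families with at least 5 detected probes whose direction was the same with each of the 16 samples left out, or else the 3 of smallest p, and a fixed panel of 33 nutrient cycling families. At most 3 probes per direction were named, by gene and source organism. Families with fewer than 5 detected probes, the families at the ends of a range, the genes with most called probes, and the Fusobacteria fall outside this rule and were named after their values were seen.

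The groups, the contrasts, the lists, the panel, the thresholds and most alternatives were chosen before the data were examined. Chosen afterwards were 4 alternatives (leaving out values under the common floor of 251.2, only families with at least 5 detected probes, sums without the probe of largest summed intensity of each family, and removal of an intensity trend from each sample before probes were tested), and the 16 panel families given as examples, which are those with the most detected probes of each functional group. Also chosen afterwards, when an earlier version gave too long a list, was the definition of a turned direction: a change of sign counts for any called result, and for other results only where either value passed the test. By that definition 56 sign changes, in 36 of 60 uncalled named values, are not printed.

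There were 26 alternative settings and 16 that left out 1 sample each. They covered scaling to equal totals, quantile normalization, other pseudocounts and filters, the mean log2 over detected probes, probes listed in all 16 samples, undetected probes set at the lowest value, a term for the replicate number, a fit of only the groups compared, a robust fit with an intensity trend, other dissimilarities and detection limits. The interaction in alternatives used 9999 permutations. The labels do not say that replicate numbers pair plots across groups, so samples were treated as unpaired. The family and probe calls were tested on simulated data with 200 changed families or probes. The simulated noise was normal and independent between families or probes, without differences in array brightness. More families were changed than passed in the data as deposited, which eases the adjusted threshold. The rates below therefore do not carry over directly to these data. For both treatments against control, 47.8%, 88.1% and 97.0% of families changed by log2 0.2, 0.5 and 1 were recovered among 944, with 8 false of 163 calls; of probes, 0%, 46.3% and 97.0% among 39102, with 7 false of 102 calls. For the nitrogen main effect 73.1%, 94.0% and 98.5% of families were recovered, with 7 false of 184 calls, and 2.99%, 94.0% and 100% of probes, with 9 false of 140 calls. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6. Nothing in the table was left out other than the families and probes under these filters.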

Results

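Genomic DNA from mangrove sediment was hybridised to a GeoChip, a microarray on which each probe stands for a functional gene of a named source organism. The sediment came from field plots in a factorial design of nitrogen addition and warming: untreated control plots, plots with added nitrogen, warmed plots, and plots that received both. Each of the 4 groups had 4 samples, 1 per plot, for 16 arrays in all. The table listed 72416 probes in 1085 gene families that cover carbon, nitrogen, sulfur and phosphorus cycling, metal homeostasis, degradation of organic contaminants, stress, virulence and viruses. Of these probes, 34861 had a listed intensity in all 16 samples and 20660 had none in any sample. A sample had between 39256 and 49136 probes with a listed intensity, and its summed intensity lay between 76229580 and 86051440 on the deposited scale. The comparisons address whether nitrogen enrichment and warming, alone and together, altered the functional gene content of the sediment community.

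The nitrogen main effect, which averages over unwarmed and warmed plots, asked whether nitrogen enrichment altered the gene content of the sediment. Added nitrogen went with a higher summed intensity of 26 gene families and a lower one of 4. Most of these were families with fewer than 5 detected probes, and some did not rise with nitrogen alone. The CRISPR family cmr1, a subunit of an effector complex that cuts foreign RNA, rose 1.33-fold, and the family of sulfate transporters, which carry sulfate into the cell, rose 1.32-fold. The polycyclic aromatic degradation family phdk rose 1.32-fold, assa (alkylsuccinate synthase, which starts the anaerobic breakdown of alkanes) rose 1.16-fold, and hcnB (a subunit of hydrogen cyanide synthase) rose 1.16-fold. Each of these families also had more listed probes with nitrogen, cmr1 a mean of 10.25 in nitrogen samples against 5 in control. Over probes listed in all 16 samples cmr1 was lower and the calls of the others were lost. As mean log2 over detected probes each of them was lower. GAPDH_Parabasalia, a glycolytic gene of parabasalid protists that serves as a phylogenetic marker on the array, fell by 0.23 on the log2 scale, but was at -0.10 and not called without its brightest probe. CsoS1_CcmK, the shell proteins of the carboxysome, fell by 0.14 on the log2 scale, but was higher by 0.09 after quantile normalization, where the median of all families was 0.19, and at 0.012 without its brightest probe.

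The summed intensity of cmr1 was 3211 ± 483 in control, 3915 ± 574 in warmed, 4438 ± 180.0 in nitrogen and 5113 ± 467 in nitrogen plus warming samples (SD, n = 4 each). The nitrogen main effect on cmr1 was 0.41 ± 0.08 (log2, SE; limma adjusted p = 0.00582), and 8 of 8 nitrogen samples lay above the mean of the samples without nitrogen. The sulfate transporter family rose by 0.40 ± 0.09 (adjusted p = 0.0214; above that mean in 7 of 8 samples), with 2988 ± 302 in control, 2990.5 ± 457 in warmed, 3501 ± 546 in nitrogen and 4648 ± 716 in nitrogen plus warming samples. phdk rose by 0.40 ± 0.09 (adjusted p = 0.0252), assa by 0.21 ± 0.05 (adjusted p = 0.0161) and hcnB by 0.21 ± 0.05 (adjusted p = 0.0172), each above that mean in 8 of 8 nitrogen samples. GAPDH_Parabasalia averaged 15688 ± 655 in control, 16846 ± 717 in warmed, 14378 ± 595 in nitrogen and 13403 ± 892 in nitrogen plus warming samples. Its main effect was -0.23 ± 0.04 (adjusted p = 0.00262), with 8 of 8 nitrogen samples below the mean of the others. A probe for Metadevescovina cuspidata gave 46.1% of its intensity, and without that probe the effect was -0.10 and not called. CsoS1_CcmK had an effect of -0.14 ± 0.03 (adjusted p = 0.0271; 8 of 8 below), and 50.9% of its intensity came from a probe for Citrobacter rodentium. This probe carried the fall: the other probes of the family summed to 162160 ± 7181 in control, 171210 ± 8753 in warmed, 168740 ± 4581 in nitrogen and 167260 ± 8529 in nitrogen plus warming samples, an effect of 0.012.

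In all, 30 of 944 families passed in limma for the nitrogen main effect, 26 higher and 4 lower. Of these, 23 were families with fewer than 5 detected probes, and 7, those named above, had at least 5. Among the 23 were cia, exsA and ler, which did not rise with nitrogen alone. Against control cia differed by -0.07 and ler by -0.04 (log2), and exsA was blank in both groups. cia was blank only in samples warmed without nitrogen, and exsA was listed only with both treatments. Blank groups with a spread of 0, as for cia, exsA and VP7_Gserotype_Rotavirus, lower the p. The count depended on the scaling and the summary: 90 families passed at equal totals and 748, all higher, after quantile normalization, while 538 passed as mean log2 over detected probes, 530 of them lower. Without the brightest probe of each family 21 of 734 passed, 8 of them among the 30. The detected part of the rising families also grew: cmr1 had a mean of 5 detected probes in control and 6.5 in warmed samples, 10.25 in nitrogen and 12.25 in nitrogen plus warming samples, out of 33 on the array. Over the probes listed in all 16 samples cmr1 (3 probes) turned to -0.15, and the calls of sulfate_transporter (0.055), phdk (0.017), assa (0.055) and hcnB (0.083) were lost. GAPDH_Parabasalia lost its call after quantile normalization (-0.047). As a mean of log2 values over detected probes cmr1 (-0.48), sulfate_transporter (-0.16), phdk (-0.23), assa (-0.52) and hcnB (-0.15) were each lower with nitrogen. When values below the highest of the samples' lowest values (251.2, called the common floor) were left out, 9 families passed, with GAPDH_Parabasalia (-0.24) among them and cmr1 (0.29), sulfate_transporter (0.24), phdk (0.36), assa (0.16), hcnB (0.19) and CsoS1_CcmK (-0.15) not. With 1 sample left out, the sulfate transporter call was lost without nitrogen plus warming replicate 1 (lowest value over the 16 samples left out 0.36). The phdk call was lost without control replicates 1, 3 and 4, warming replicates 2 and 3, nitrogen replicates 1 and 3, or nitrogen plus warming replicates 1 and 4, with values from 0.36 to 0.46. The CsoS1_CcmK call was lost without control replicates 2 and 4, warming replicates 1 and 2, nitrogen replicates 1 and 2, or nitrogen plus warming replicates 1 to 3, with values from -0.16 to -0.13.

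None of the 33 families of the fixed nutrient cycling panel passed for the nitrogen main effect: 19 were higher and 14 lower, from -0.22 (gdh, glutamate dehydrogenase) to 0.18 (soxB, of sulfur oxidation). In the nitrogen cycle, nifh (nitrogenase) differed by 0.02 ± 0.03, narg (nitrate reductase) by 0.01 ± 0.03, nosz (nitrous oxide reductase) by 0.01 ± 0.04 and urec (urease) by 0.01 ± 0.03 (log2, SE). In methane cycling, mcra (methyl-coenzyme M reductase of methanogens) differed by -0.05 ± 0.03 and pmoa (particulate methane monooxygenase) by -0.03 ± 0.04, while rubisco differed by 0.04 ± 0.06. Of the sulfur genes, aps_apra (adenylylsulfate reductase) differed by 0.01 ± 0.04 and dsrB (dissimilatory sulfite reductase) by -0.01 ± 0.04. The polyphosphate genes ppx and ppk differed by -0.02 ± 0.03 and -0.01 ± 0.03, and the starch, chitin and xylan degradation genes amyA, chitinase and xylanase by -0.03 ± 0.03, -0.01 ± 0.03 and -0.0022 ± 0.04. The single-copy marker gyrB differed by 0.02 ± 0.04, and the median over all 944 families was 0.0067. These signs depended on the scaling: after quantile normalization all 33 panel families were higher and 31 passed, at equal totals 24 were higher and 3 passed, over probes listed in all 16 samples 28 were lower, and as mean log2 over detected probes all 33 were lower and 29 fell.

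Samples with added nitrogen had more detected probes. The mean number was 42107 ± 1964 in control, 41114 ± 1089 in warmed, 45922 ± 1973 in nitrogen and 47266 ± 1808 in nitrogen plus warming samples (SD, n = 4). The nitrogen main effect was 4984 ± 873 probes (SE; exact permutation p = 0.000816, adjusted over the 6 contrasts 0.0049), and 7 of 8 nitrogen samples had more probes than every sample without nitrogen. Bacterial probes, 65363 of the 72416 on the array, went from a mean of 38661 detected in control to 42099 in nitrogen samples. Fungal probes went from 1592 to 1778, archaeal from 929.5 to 1019.8 and viral from 301.5 to 343.8, so the rise was not particular to Bacteria. The lowest listed intensity moved with it, at 217.8 ± 11.5 in control, 246.5 ± 5.41 in warmed, 188.6 ± 14.6 in nitrogen and 187.3 ± 11.5 in nitrogen plus warming samples, a main effect of -44.2 ± 5.63 (exact permutation p = 0.000408, adjusted 0.00245; lower in 8 of 8 samples). Above the 10th percentile of all listed values (304.2), the nitrogen main effect on the number of probes was 482 ± 697 (exact permutation p = 0.49).

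**Figure D1:**
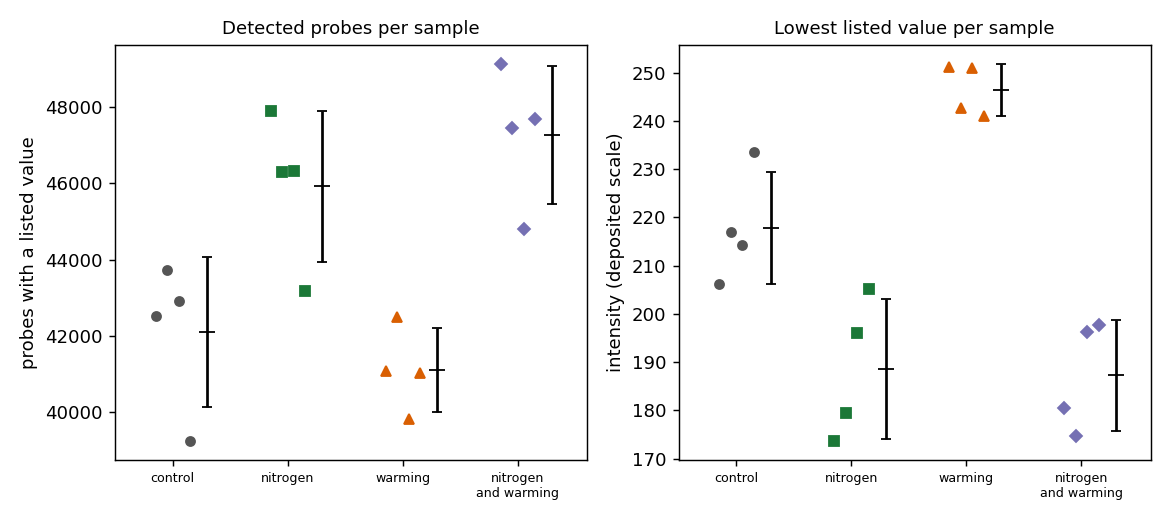
Number of probes with a listed intensity (left panel) and lowest listed intensity on the deposited scale (right panel), on axes that do not start at 0, with 1 point for each of the 16 samples by group; bars give the mean and SD of 4 samples. Means of 45922 and 47266 probes with nitrogen stood above 42107 and 41114 without it, while the lowest listed value averaged 188.6 and 187.3 with nitrogen and 217.8 and 246.5 without.

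Community composition as measured on the arrays differed between plots with and without added nitrogen. Blanks counted as 0 here, so the difference in the number of detected probes enters this dissimilarity. How much of the result it makes up was not tested: the alternative dissimilarities, scalings and limits also counted blanks as 0, so they do not separate it. Nitrogen took 17.5% of the variation in Bray-Curtis dissimilarity over all probes (permutational multivariate test, pseudo-F = 3.23, exact permutation p = 0.000408, the smallest the arrangements allow, adjusted over 3 terms 0.00122). The samples with both treatments lay farther from control samples (mean dissimilarity 0.0765 ± 0.0124 over 16 pairs) than the control samples lay from each other (0.0601 ± 0.00717 over 6 pairs), but also lay farther from each other (0.0706 ± 0.00985 over 6 pairs). Among 38 lineage groups, Fusobacteria, anaerobic bacteria, were higher with nitrogen by 0.79 ± 0.12 (log2, SE; limma adjusted p = 9.04e-05), with 8 of 8 nitrogen samples above the mean of the others, but 6 of 100 splits of the samples, the real one included, gave at least 1 called group (highest other 17). Their summed intensity was 987 ± 68.0 in control, 687 ± 80.4 in warmed, 1436 ± 226 in nitrogen and 1495 ± 483 in nitrogen plus warming samples. This rested on few probes: of 30 for Fusobacteria, a mean of 2.75 was detected in control and 4.75 in nitrogen plus warming samples, and 1 in all 16, from Sebaldella termitidis, at 428.6 in control, 367.2 in warmed, 440.8 in nitrogen and 377.7 in nitrogen plus warming samples. No domain passed, with differences of -0.02 ± 0.03 for Bacteria, -0.0049 ± 0.03 for Archaea, -0.0052 ± 0.03 for Fungi and 0.02 ± 0.04 for Viruses. Of 39102 probes tested one by one with limma, 0 passed for the nitrogen main effect and 4918 had an unadjusted p under 0.05, but 15977 passed after quantile normalization and 171 with undetected values at the lowest value of the sample.

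**Figure D2:**
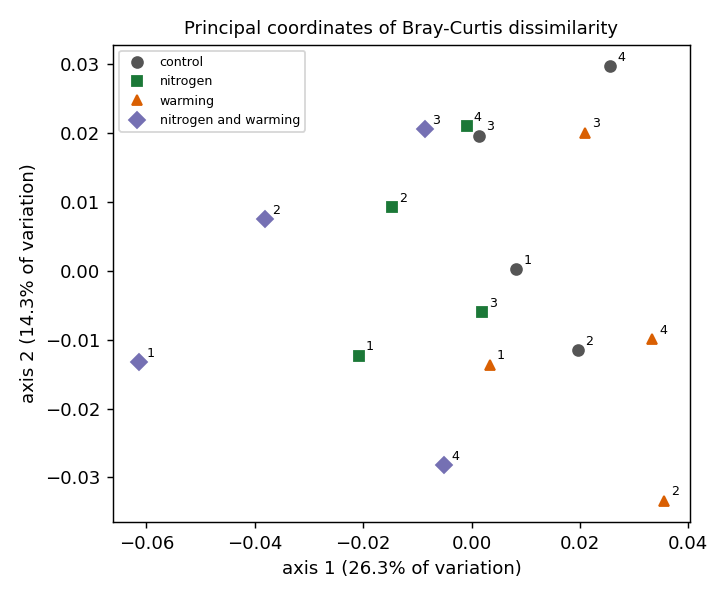
Principal coordinates of Bray-Curtis dissimilarity over all probes, with axis 1 (26.3% of variation) against axis 2 (14.3%); each point is a sample, marked by group and replicate number. The 4 samples with nitrogen and warming lie between -0.0613 and -0.00505 on axis 1, and the control samples between 0.00135 and 0.0256.

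Plots with both treatments, against the control, asked what nitrogen and warming did together. They had a higher summed intensity of 17 gene families and a lower one of 3. cmr1 rose 1.56-fold and csy1, a subunit of another CRISPR effector complex, rose 1.22-fold. The sulfate transporters rose 1.51-fold and Cyanide_hydratase_Fungi, a fungal enzyme that detoxifies cyanide, rose 1.23-fold. GAPDH_Parabasalia fell by 0.23 on the log2 scale, and was at -0.075 and not called without its brightest probe. These directions were the same under scaling to equal totals and quantile normalization, although GAPDH_Parabasalia was at -0.061 in the latter and lost its call. Over the probes listed in all 16 samples cmr1 (-0.12) and Cyanide_hydratase_Fungi (-0.035) were lower and sulfate_transporter (0.23) lost its call, and as a mean of log2 values over detected probes cmr1 (-0.55), sulfate_transporter (-0.10), Cyanide_hydratase_Fungi (-0.15) and csy1 (-0.24) were each lower.

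For cmr1 the difference was 0.64 ± 0.11 (log2, SE; limma adjusted p = 0.00501), with 4 of 4 treated samples above every control. The sulfate transporter family rose by 0.59 ± 0.13 (limma adjusted p = 0.0244, 4 of 4 above every control). Its probes that were listed in at least 3 of these 4 samples and in no control came from the fungi Magnaporthe grisea, Aspergillus terreus, Schizosaccharomyces japonicus and Penicillium chrysogenum. Cyanide_hydratase_Fungi rose by 0.30 ± 0.05 (adjusted p = 0.00654; 4 of 4 above every control), from 20406 ± 518 to 25190 ± 1800 (SD, n = 4), and csy1 by 0.28 ± 0.06 (adjusted p = 0.0207; 4 of 4 above every control), from 9642 ± 734 to 11760 ± 419.7. GAPDH_Parabasalia differed by -0.23 ± 0.05 (adjusted p = 0.0414; 4 of 4 below every control). In limma 20 families passed, 17 higher and 3 lower, of which 5 had at least 5 detected probes. The count was 50 at equal totals, 585 after quantile normalization and 260, of which 248 lower, as mean log2 over detected probes. Under the common floor 7 families passed, Cyanide_hydratase_Fungi among them at 0.30, while cmr1 (0.54), sulfate_transporter (0.44), csy1 (0.25) and GAPDH_Parabasalia (-0.23) did not. The sulfate transporter call was lost without control replicates 1, 3 and 4 or nitrogen plus warming replicates 1 and 4 (0.52 to 0.69 over all 16 samples left out), and the csy1 call without control replicates 3 and 4 or nitrogen plus warming replicate 1 (0.24 to 0.32). The GAPDH_Parabasalia call was lost without control replicates 2 to 4, warming replicates 3 and 4, nitrogen replicates 1 and 2, or nitrogen plus warming replicates 1 and 2 (-0.25 to -0.18). The count of families was 12 without control replicate 4, 11 without nitrogen plus warming replicate 1 and 31 without nitrogen plus warming replicate 3.

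**Figure D3:**
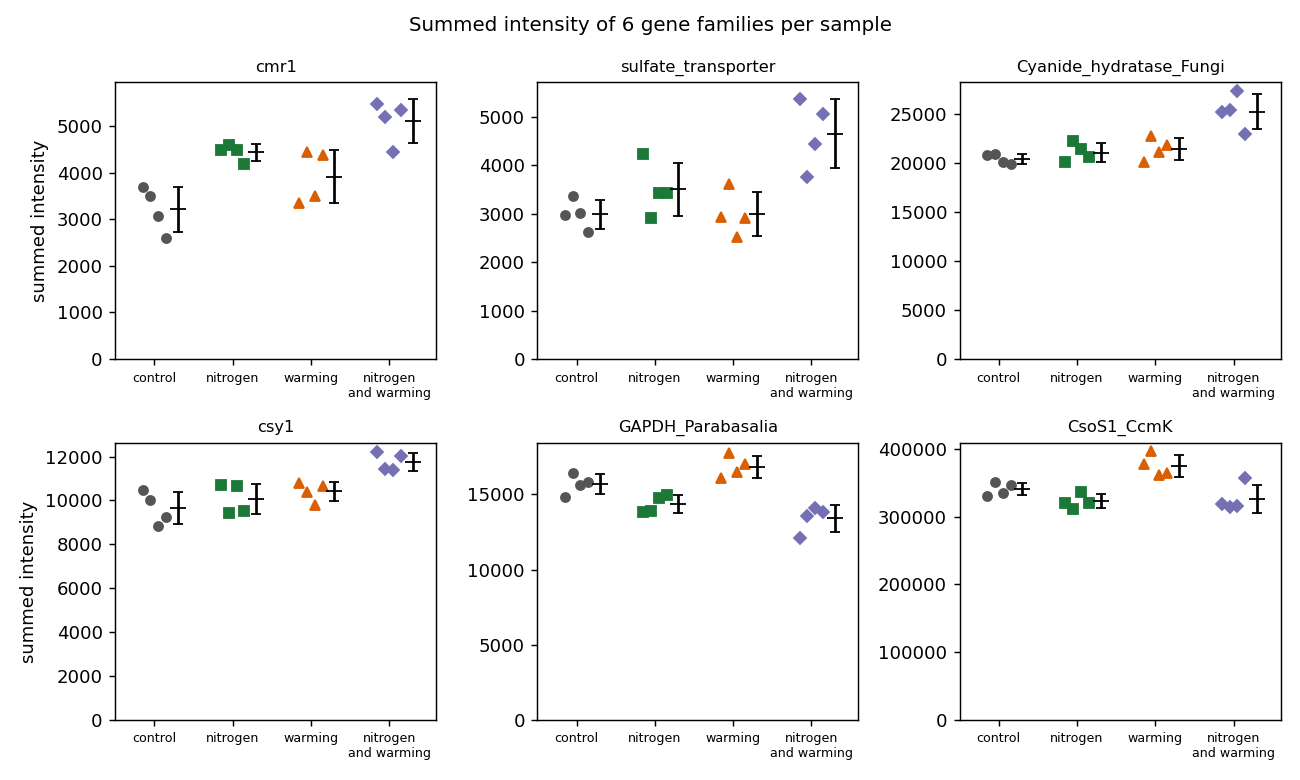
Summed intensity (deposited scale) of the 6 gene families cmr1, sulfate_transporter, Cyanide_hydratase_Fungi, csy1, GAPDH_Parabasalia and CsoS1_CcmK in each sample (points) by group; bars give the mean and SD of 4 samples. cmr1 averaged 3211 in control and 5113 in nitrogen plus warming samples, and GAPDH_Parabasalia 15688 and 13403; CsoS1_CcmK is lower with nitrogen here but higher by 0.09 after quantile normalization and by 0.012 without its brightest probe, and cmr1, sulfate_transporter, Cyanide_hydratase_Fungi and csy1 turn lower as mean log2 over detected probes.

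Single probes also changed under the combined treatment: 184 of 39102 passed in limma, 160 higher (by 0.37 to 1.62) and 24 lower (by -1.69 to -0.44). The count and its split depended on the scaling: 415 passed at equal totals, 306 higher and 109 lower, 6845 after quantile normalization, 6799 of them higher, and 789 with undetected values at the lowest value of the sample, 620 of them higher. The probes with the smallest p among the higher ones were ChrA, a chromate transporter, from Aeromonas caviae (0.90 ± 0.10, adjusted p = 0.00142), sigma_24, an extracytoplasmic stress sigma factor, from Pseudoxanthomonas suwonensis (0.84 ± 0.10, adjusted p = 0.00142) and amyA, an alpha-amylase, from Microlunatus phosphovorus (0.81 ± 0.10, adjusted p = 0.00366). Each was above every control in 4 of 4 samples. The lower ones were led by sigma_24 from Methylobacterium nodulans (-0.69 ± 0.10, adjusted p = 0.00702), znuC, of zinc uptake, from Arthrobacter chlorophenolicus (-0.65 ± 0.10, adjusted p = 0.0103) and lycopene_beta_cyclase, of carotenoid synthesis, from a Bradyrhizobium strain (-1.23 ± 0.22, adjusted p = 0.0223), each below every control in 4 of 4 samples. By gene, MFS_antibiotic (efflux pumps of the major facilitator superfamily) had 12 of these among 3038 probes tested and amyA 6 among 1256, all higher. The share of MFS_antibiotic was under that of all probes (184 of 39102) and the share of amyA close to it. Enrichment was not tested by gene. With an intensity trend removed from each sample, 360 probes passed, 236 higher and 124 lower. The count also moved with single samples: it was 38, 109, 31 and 85 without control replicates 1 to 4, and 90, 51, 506 and 108 without nitrogen plus warming replicates 1 to 4.

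The combined treatment raised the number of detected probes by 5159 ± 1335 (SE; exact permutation p = 0.0286, the smallest that 4 against 4 samples allow, adjusted 0.0857), with 4 of 4 samples above every control. There were 1208 probes listed in all 4 of these samples and in no control, and 35 the other way. Under the common floor these were 588 and 36. Chance would give 24.9 in each direction if all samples listed probes equally often. The samples with both treatments listed more, so this reference does not account for the number of listed probes. No probe was listed in exactly 1 of the 16 samples, so single listings may have been removed before deposit. If that was done within groups, the reference is too low. This is not known. Above the 10th percentile of listed values the difference was 1406 probes (exact permutation p = 0.314). Composition gave an R2 of 29.4% for this pair (exact permutation p = 0.0286, adjusted 0.0857). The adjusted values did not pass.

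None of the 33 panel families passed under the combined treatment, where 28 were higher and 5 lower, from -0.21 (gdh) to 0.27 (AprA). Without the brightest probe of each family 31 were higher and 2 lower, from -0.05 (mcra) to 0.32 (AprA). The value of gdh thus rested largely on its brightest probe. nifh differed by 0.03 ± 0.04, narg by 0.04 ± 0.04, nosz by 0.05 ± 0.05, mcra by -0.04 ± 0.05, rubisco by 0.10 ± 0.09, dsra by 0.05 ± 0.05 and gyrB by 0.02 ± 0.06 (log2, SE). After quantile normalization all 33 were higher and 27 passed, over probes listed in all 16 samples 24 were lower, and as mean log2 over detected probes all 33 were lower and 21 fell.

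No functional gene list moved as a set under the combined treatment. limma's camera with its preset correlation called 0 of 25 lists, with a smallest adjusted p of 0.859 (0.966 with an estimated correlation) and 0 lists at an unadjusted p under 0.05. Median log2 differences of the nitrogen lists were 0.03 for nitrification (3 families), 0.05 for denitrification (6), 0.09 for dissimilatory nitrate reduction to ammonium (3), 0.02 for assimilatory nitrate reduction (5) and 0.01 for nitrogen limitation (4). For carbon they were 0.03 for methanogenesis (8), 0.04 for carbon fixation (11), 0.01 for starch degradation (8), 0.02 for cellulose and hemicellulose degradation (9), 0.01 for chitin degradation (3), 0.0088 for pectin degradation (11) and 0.04 for lignin and aromatic compound degradation (8). Sulfate and sulfite reduction had 0.05 (9), sulfur oxidation 0.07 (7), phosphorus cycling 0.0037 (3) and phosphate limitation -0.0078 (6). Among stress lists the medians were 0.03 for heat shock (7), -0.03 for cold shock (4), 0.0028 for oxidative stress (9), 0.03 for osmotic stress (4) and 0.03 for sigma factors (4). Arsenic resistance had -0.0013 (5), mercury resistance 0.04 (4), other metal resistance 0.03 (24) and antibiotic resistance -0.0058 (11), beside a median of 0.03 over all families. In several of these lists camera gave the direction down with a positive median, since it compares a list with the other families. Across the 180 families on the lists, 0 passed over all families tested, 0 passed adjusted over the list alone, and 13 had an unadjusted limma p under 0.05; for the nitrogen main effect these counts were 2 (CsoS1_CcmK and pcc_3HP, both of carbon fixation), 0 and 14. Taken list by list, 1 heat shock family passed with both treatments, 2 carbon fixation families for the nitrogen main effect and 1 osmotic stress family for the interaction.

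Nitrogen addition without warming was set against the control to ask what nitrogen did on its own. In limma 1 gene family passed, a count that other splits of the samples also reached (4 of 35, the real one included). The count was 0 under the common floor, with 10 times the pseudocount and over probes listed in all 16 samples (33, 52 and 20 families at an unadjusted p under 0.05), and without the brightest probe of each family (54), but 3 at equal totals, 38 as mean log2 over detected probes and 87 after quantile normalization. The family was VP7_Gserotype_Rotavirus, a family of rotavirus capsid protein genes with 4 probes, at most 2 of them detected, which was blank (not detected) in all control and warmed samples and averaged 270.5 ± 38.0 in nitrogen samples (SD, n = 4). Its log2 difference is set by the pseudocount and is not given as a size. Of families with at least 5 detected probes, 0 passed. Where only the 435 families with at least 10 detected probes were tested, 1 passed, higher with nitrogen. The smallest p among families with at least 5 belonged to cmr1, with a difference of 0.45 ± 0.11 (log2, SE, limma adjusted p = 0.104). Next were exopolygalacturonase_fungi, of pectin breakdown, with 0.17 ± 0.05 (adjusted p = 0.393), and assa with 0.19 ± 0.06 (adjusted p = 0.472). In limma 52 families had an unadjusted p under 0.05. The count of called families was 8 without nitrogen replicate 4, and 2 without any warming sample, nitrogen replicates 1 and 2, or any nitrogen plus warming sample.

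The panel families differed by -0.18 (gdh) to 0.13 (soxB) with nitrogen alone, 25 higher and 8 lower, and 0 passed. Without the brightest probe of each family the lowest value was -0.068 (amoa), so the value of gdh rested largely on its brightest probe. After quantile normalization all 33 were higher and 2 passed, over probes listed in all 16 samples 21 were lower, and as mean log2 over detected probes all 33 were lower and 1 fell. Nitrogen samples had 3816 ± 1392 more detected probes (SE; exact permutation p = 0.0571, adjusted 0.114; 3 of 4 above every control), and the R2 of this pair was 22.1% (exact permutation p = 0.0571, adjusted 0.0857). There were 525 probes listed in all 4 nitrogen samples and in no control, and 24 the other way (206 and 26 under the common floor). Chance would give 16.4 in each direction if all samples listed probes equally often, which they did not. It is also too low if single listings were removed within groups before deposit. limma called 0 probes, with 1533 at an unadjusted p under 0.05, and camera called 0 of 25 lists, with 0 at an unadjusted p under 0.05 and list medians from -0.01 (pectin degradation) to 0.09 (methanogenesis).

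Warming without nitrogen was set against the control to ask what warming did on its own. In limma 2 families passed, both with few detected probes, a count that other splits of the samples also reached (2 of 35, the real one included). The count was 0 under the common floor and over probes listed in all 16 samples (69 and 63 families at an unadjusted p under 0.05), and with at least 5 or 10 detected probes (27 and 15), but 10 as mean log2 over detected probes, 9 of them higher. toxR, a regulator of virulence genes with at most 4 detected probes, rose from 1126 ± 60.6 to 1603 ± 92.9 (SD, n = 4; log2 difference 0.44 ± 0.07, limma adjusted p = 0.0126). cia, an invasion antigen family with 1 detected probe, averaged 290.2 ± 14.3 in control samples and was blank (not detected) in 4 of 4 warmed samples, so that its log2 difference is set by the pseudocount. Of families with at least 5 detected probes, 0 passed. Those with the smallest p were impH, of type VI secretion, with 0.25 ± 0.08, cmua, a chloromethane methyltransferase, with 0.19 ± 0.06, and asr, of acid shock, with 0.34 ± 0.11 (log2, SE; adjusted p = 0.459 for each). The count of called families was 1 without control replicate 3 or warming replicates 1, 3 and 4, and 4 without nitrogen replicate 4.

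Panel families lay between -0.03 (norb, nitric oxide reductase) and 0.50 (hao, hydroxylamine oxidoreductase, 33465 ± 24154 in warmed samples) with warming, 29 higher and 4 lower, with 0 past the test; after quantile normalization 3 were higher and 30 lower, and at equal totals 21 were higher and 12 lower. The value of hao depended on which probes were summed: without its brightest probe it was 0.97. Over probes listed in all 16 samples the highest panel value was 0.079 (amyA). The SD of hao in warmed samples was large beside its mean, and hao was not among the values searched for an outlying sample. Its value may thus rest on few samples, which was not tested. limma gave 69 families and 4421 probes at an unadjusted p under 0.05, and 0 probes passed. The median difference of probes listed in all samples ran from 0.11 in the dimmest 10% to 0.02 in the brightest 10%. The difference in detected probes was -993 ± 1123 (SE; exact permutation p = 0.4, adjusted 0.48), which turned to 1040.5 above the 10th percentile of listed values, and the lowest listed value was higher by 28.7 ± 6.36 (exact permutation p = 0.0286, adjusted 0.0343; 4 of 4 above every control). There were 221 probes listed in all controls and no warmed sample, and 73 the other way (197 and 74 under the common floor). Chance would give 16.2 in each direction if all samples listed probes equally often. This reference is too low if single listings were removed within groups before deposit, which is not known. The R2 of this pair was 20.3% (exact permutation p = 0.114, adjusted 0.114), and camera called 0 of 25 lists, with 0 at an unadjusted p under 0.05 and list medians from -0.02 (nitrification) to 0.06 (dissimilatory nitrate reduction to ammonium).

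**Figure D4:**
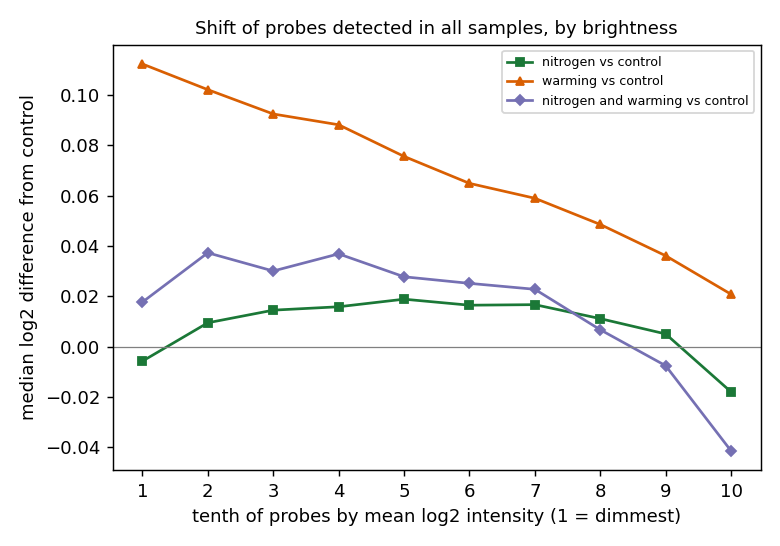
Median log2 difference from control of the probes listed in all 16 samples, in 10 classes of mean log2 intensity from the dimmest (1) to the brightest (10), for the 3 treated groups. With warming the median is 0.11 in the dimmest class and 0.02 in the brightest; with nitrogen and warming it is 0.02 and -0.04.

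The warming main effect asked whether warming altered gene content over both nitrogen levels. It passed for 4 families, all with fewer than 5 detected probes: cia, exsA, ler and toxR in limma. Of these, cia, exsA and ler differed with warming at 1 nitrogen level only. cia was blank only in samples warmed without nitrogen, and exsA was listed only with both treatments. ler averaged 583 with both treatments, against 404 in control, 391 in warmed and 386 in nitrogen samples. For cia and exsA, blank groups with a spread of 0 lower the p. With 10 times the pseudocount, in a trended and robust fit, under the common floor, and with at least 5 or 10 detected probes, limma called 0 (70, 68, 63, 34 and 25 families at an unadjusted p under 0.05). Other families passed elsewhere. Without the brightest probe of each family 4 passed, 0 of them among the 4 above. Over probes listed in all 16 samples 3 passed, 1 of them among the 4 above. Among the families with at least 5, 0 passed, and those with the smallest p were Cyanide_hydratase_Fungi with 0.16 ± 0.04 (adjusted p = 0.114), csy1 with 0.17 ± 0.04 (adjusted p = 0.168) and APS_kinase_protist, of sulfate assimilation, with 0.21 ± 0.06 (adjusted p = 0.201; log2, SE). Panel families ranged from -0.05 (soxA) to 0.23 (hao; 0.50 without its brightest probe), 29 higher and 4 lower, and 0 passed. pmoa differed by 0.07 ± 0.04, nosz by 0.05 ± 0.04, dsra by 0.05 ± 0.03, amyA by 0.04 ± 0.03 and gyrB by 0.0045 ± 0.04. In limma 71 families had an unadjusted p under 0.05. The count of called families was 7 without control replicate 2, 1 without nitrogen plus warming replicates 1 or 2, and 2 without control replicate 3, warming replicates 1, 3 or 4, nitrogen replicate 3 or nitrogen plus warming replicate 3.

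At the level of probes, 68 passed for the warming main effect, 59 higher (by 0.29 to 1.02) and 9 lower (by -1.10 to -0.35). After quantile normalization 15 passed, 11 of them higher, and 594 passed with undetected values at the lowest value of the sample, 520 of them higher. A pectinase (pectate_lyase) probe from the plant pathogen Colletotrichum gloeosporioides rose by 0.67 ± 0.08 and mgtA, a magnesium transporter, from Desulfonatronospira thiodismutans rose by 0.60 ± 0.08, each above every unwarmed sample in 8 of 8 warmed samples (limma adjusted p = 0.00402 for both). ChrA from Aeromonas caviae rose by 0.54 ± 0.07 (adjusted p = 0.00402; 7 of 8). znuC from Arthrobacter chlorophenolicus fell by 0.45 (adjusted p = 0.0189; 8 of 8 below every unwarmed sample), kefBC, of potassium efflux, from a Shewanella strain fell by 0.53 (adjusted p = 0.0244; 8 of 8 below the unwarmed mean), and fiu, of iron uptake, from a Bradyrhizobium strain fell by 0.54 (adjusted p = 0.0244; 8 of 8 below that mean). With an intensity trend removed from each sample, 34 probes passed, 20 higher and 14 lower, 27 of them among the 68. The count was 22, 23 and 44 without control replicates 1, 3 and 4, 43, 12 and 36 without warming replicates 1 to 3, 19 and 36 without nitrogen replicates 2 and 3, and 40, 22, 163 and 32 without nitrogen plus warming replicates 1 to 4.

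Warming took 8.57% of the variation in composition (exact permutation p = 0.0478, adjusted 0.0607), which did not pass after adjustment. Its main effect on the number of detected probes was 175 ± 873 (SE; exact permutation p = 0.851). Of 38 lineage groups limma called 0, with 1 at an unadjusted p under 0.05; the differences ran from -0.26 (Fusobacteria) to 0.05 (Apicomplexa). camera called 0 of 25 lists, with 0 at an unadjusted p under 0.05 and list medians from -0.03 (nitrogen limitation) to 0.05 (mercury resistance).

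The interaction asked whether the response to nitrogen differed between warmed and unwarmed plots. It passed for 4 families with at most 1 detected probe each: cia, exsA, ler and xylm; the count was 2 without nitrogen plus warming replicates 1, 3 or 4. limma called 0 with 10 times the pseudocount, in a trended and robust fit, and with at least 5 or 10 detected probes (65, 67, 21 and 11 families at an unadjusted p under 0.05), and 1 under the common floor. Of families with at least 5 detected probes 0 passed, and those with the smallest p were hfq_5f0_stress, an RNA chaperone, with -0.29 ± 0.08, trza, a triazine hydrolase, with 0.55 ± 0.17, and algB, a regulator of alginate synthesis, with -0.24 ± 0.08 (log2, SE; limma adjusted p = 0.357 for each). The panel ranged from -0.53 (hao; -0.94 without its brightest probe) to 0.09 (soxB), 9 higher and 24 lower, with 0 past the test. At equal totals 18 were higher, after quantile normalization 30, and as mean log2 over detected probes all 33 were lower. In limma 73 families and 3908 probes had an unadjusted p under 0.05, and 0 probes passed. camera called 0 of 25 lists; cold shock alone had an unadjusted p under 0.05 (0.0411; adjusted 0.963, 0.984 with an estimated correlation), with 4 of 4 families lower and a median of -0.10. The interaction took 8.81% of the variation in composition (permutation p = 0.0607, adjusted 0.0607). The unadjusted permutation p was 0.0275 on relative abundance, 0.0072 with Jaccard dissimilarity, 0.0032 with Hellinger distance and 0.0134 with Jaccard above the common floor. The interaction in the number of detected probes was 2336 ± 1747 (SE; permutation p = 0.175, adjusted 0.263), which turned to -233.5 above the 10th percentile.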

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

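The tests of detection limits, array brightness, the common floor and the intensity trend below were chosen only after the results they concern had been seen, whereas the splits of the samples were set before.

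Samples with added nitrogen had more detected probes (4984 ± 873, SE). A single sharp limit that differs between samples is argued against, because 2729 ± 770 more probes remained above the common floor (exact permutation p = 0.00286). A limit that is not sharp, so that weak probes come and go with array brightness, may account for it, since above the 10th percentile of listed values the main effect was 482 ± 697 (exact permutation p = 0.49). Array brightness as read from the lowest listed value stays open: after group means were removed, samples with a higher lowest value had fewer probes (16 samples, Pearson r = -0.734, permutation p = 0.00929; Spearman rho = -0.597, permutation p = 0.038; r = -0.531 without the 2 farthest samples), and -1.14% of the main effect was left after the slope within groups was removed, but with a standard error of 1535 probes, and the lowest value itself differed with nitrogen. The highest listed value moved with the lowest. It lay between 205299 and 259068 in samples without nitrogen and between 170700 and 205310 in samples with it. The lowest value may thus follow the scale of a whole array rather than a detection limit, which was not tested. The common floor takes the deposited scale to be equal between samples. An effect of nitrogen on rare members of the community also stays open and was not tested.

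Most families called for nitrogen and for both treatments had few detected probes, 23 of 30 and 15 of 20. Single weak probes that pass or miss the detection limit may account for part of this: of the 30 families, 9 were also called under the common floor, and of the 20, 7 were. Among named families whose call ended there, the nitrogen main effect went from 0.41 to 0.29 for cmr1 and from 0.40 to 0.24 for sulfate_transporter, but phdk (0.40 to 0.36), hcnB (0.21 to 0.19) and CsoS1_CcmK (-0.14 to -0.15), and with both treatments csy1 (0.28 to 0.25) and GAPDH_Parabasalia (-0.23 to -0.23), stayed about as large, which the explanation does not account for. Cyanide_hydratase_Fungi with both treatments and GAPDH_Parabasalia for the nitrogen main effect were called under the common floor, but over probes listed in all 16 samples the former was -0.035, and after quantile normalization the latter was -0.047 and not called. An effect of the treatments on these families stays open and was not tested further.

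Of the probes called for warming, 86.8% were higher. A shift of weak probes that depends on intensity may account for part of this: with an intensity trend removed from each sample, 27 of the 68 probes were called, the calls that were higher went from 59 to 20 and those that were lower from 9 to 14, and the median size of called differences went from 0.45 to 0.39. With both treatments the same step raised the calls in both directions, from 160 to 236 higher and from 24 to 124 lower, so the shift does not account for the higher calls there. The named probes of the warming main effect changed little in size (pectinase (pectate_lyase) of Colletotrichum gloeosporioides from 0.67 to 0.60, znuC of Arthrobacter chlorophenolicus from -0.45 to -0.52), and an effect of warming on them stays open.

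Other splits of the same samples were fitted to see whether chance gives as many calls. For both treatments against control, 1 of 35 splits, the real one, gave as many families (20, highest other 1). The same held for probes (1 of 35, real count 184, highest other 1), so chance alone seldom gives such counts. For the warming main effect, 1 of 100 splits gave as many families (4, highest other 3) and 1 of 100 as many probes (68, highest other 57). The real counts lay not far above those of other splits, which makes chance less likely but does not exclude it. For the nitrogen main effect 2 of 100 splits gave as many families (30, highest other 58), and for the interaction 2 of 100 (4, highest other 11). Both shares are small, but another split gave more calls than the real one, so chance is not excluded. For the interaction, the splits moved samples freely among all 4 groups, so main effects added to their spread. Chance was also not excluded for the families of nitrogen against control (4 of 35 splits, real count 1, highest other 2) and of warming against control (2 of 35, real count 2, highest other 2). Nor was it for the lineage groups of the nitrogen main effect (6 of 100, real count 1, highest other 17). A split with several times the real count (11 against 4, 17 against 1) points to a structure of the samples or to families and groups that move together; neither was tested. Counts of 0 calls were matched by all splits: 35 of 35 for the probes of nitrogen and of warming against control (highest other 1 each) and for the lists of the 3 comparisons with control (highest other 0), and 100 of 100 for the probes of the nitrogen main effect (highest other 6) and the interaction (highest other 0), the lineage groups of warming (highest other 1), and the lists of the main effects and the interaction (highest other 1 for nitrogen and the interaction, 0 for warming).

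In 12 of 172 groups of 4 samples, 1 sample lay far from the other 3, where chance gives about 1 in 20 (8.6). This reference takes the values to be independent, which values from the same sample may not be. The values are the gap to the nearest sample as a share of the group's range. In control replicate 2 they were 0.978 for other Eukaryota (622590 against 569260 to 570440), 0.887 for phdk (1857 against 1243 to 1313), 0.842 for algB (22365 against 19745 to 20158), 0.939 for nifh (336750 against 310200 to 311810), 0.853 for nosz (219840 against 199400 to 202410) and 0.865 for dsra (306820 against 277050 to 281070). In warming replicate 2 they were 0.865 for Viruses (414730 against 373060 to 378710) and 0.894 for Fusobacteria (807 against 637 to 655), and in nitrogen replicate 2 0.906 for cmua (5903 against 6445 to 6502). In nitrogen plus warming replicate 4 they were 0.89 for CsoS1_CcmK (356470 against 313790 to 318490), 0.856 for rubisco (288560 against 202670 to 215010) and 0.835 for amyA (2577400 against 2355800 to 2392400). Control replicate 2, warming replicate 2 and nitrogen plus warming replicate 4, each high here, also had the highest summed intensity in their groups. These were 82903730 (others 76229580 to 78916020), 86051440 (77705100 to 81257280) and 84530360 (76460620 to 78359840). Nitrogen replicate 2, low here, had the lowest in its group (76492670, others 78074890 to 80806710). The values may thus partly follow the summed intensity of the sample, which was not tested.

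The interaction passed for families with at most 1 detected probe and for the lowest listed value, but 0 families were called with 10 times the pseudocount or in a trended and robust limma fit (65 and 67 at an unadjusted p under 0.05), and 1 family was called under the common floor. It was 0.43 on the log2 scale for ler (adjusted p = 0.00813). The others were blank in whole groups, cia in warmed samples, exsA in all but nitrogen plus warming samples, and xylm in control and nitrogen plus warming samples. Their log2 values of 1.23 (cia), 1.17 (exsA) and -1.62 (xylm) are set by the pseudocount and are not measured sizes, and a spread of 0 in blank groups lowers their p, which is not given. For the lowest listed value it was -30.0 (permutation p = 0.0127, adjusted 0.0343), with 4 of 4 warmed samples above every control.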

How the results depend on the processing

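The common floor, the limit of at least 5 detected probes, the removal of an intensity trend and the sums without each family's brightest probe are tests chosen only after the results had been seen; the others were set before. Of the counts of calls, composition and detected probes under settings that keep all samples, named families not included, 137 kept their direction and side of the threshold, or their count within 1.5 times, and 73 did not. Where a cause is not given, the cause was not tested. Weak probes near the detection limit were listed in some samples and blank in others; whether signal over background, sample number or another limit mattered most was not compared.

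Scaling to equal totals gave 3 families for nitrogen, 1 for warming, 50 for both treatments and 90 for the nitrogen main effect, 415 probes for both treatments and 6 lineage groups for the nitrogen main effect. Quantile normalization gave 87 families for nitrogen, 1 for warming, 585 for both, 748 for the nitrogen main effect and 2 for the warming main effect, and 6845, 15977 and 15 probes for both, the nitrogen and the warming main effects. It moved the median of all families by 0.14 for nitrogen, 0.19 for both and 0.19 for the nitrogen main effect. By its construction it maps samples with different numbers of listed probes to the same distribution, which raises samples with more weak probes. For the nitrogen main effect it turned CsoS1_CcmK to 0.090, mcra to 0.13, pmoa to 0.15, dsrB to 0.16, ppx to 0.16, ppk to 0.17, chitinase to 0.17, xylanase to 0.18 and amyA to 0.14, all under that median.

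The mean log2 over detected probes gave 38 families for nitrogen, 10 for warming, 260 for both, 538 for the nitrogen main effect and 9 for the interaction. By its construction, newly listed weak probes lower a family's mean; the median of all families was -0.11, 0.11, -0.14, -0.19 and -0.13 in these contrasts. Turned directions were -0.52 for cmr1 and -0.50 for assa with nitrogen. With both treatments they were -0.55 for cmr1, -0.10 for sulfate_transporter, -0.15 for Cyanide_hydratase_Fungi, -0.24 for csy1, -0.19 for nifh, -0.15 for narg, -0.20 for nosz, -0.18 for urec, -0.22 for pmoa, -0.17 for dsra, -0.19 for dsrB, -0.26 for aps_apra, -0.18 for ppx, -0.22 for ppk, -0.18 for chitinase, -0.22 for xylanase, -0.19 for amyA and -0.19 for gyrB. For the nitrogen main effect they were -0.48 for cmr1, -0.16 for sulfate_transporter, -0.23 for phdk, -0.52 for assa, -0.15 for hcnB, -0.22 for nifh, -0.18 for narg, -0.24 for nosz, -0.20 for urec, -0.18 for rubisco, -0.23 for dsra, -0.28 for aps_apra and -0.23 for gyrB.

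Other ways to form families changed the counts too. With 10 times the pseudocount 0 families were called in limma for nitrogen (52 at an unadjusted p under 0.05), the warming main effect (70) and the interaction (65). With at least 10 detected probes, which left 435 families, 9 were called for both treatments and 5 for the nitrogen main effect, and 0 for warming (15 at an unadjusted p under 0.05), its main effect (25) and the interaction (11). Sums over the probes detected in all 16 samples gave 5 families for both treatments, 4 for the nitrogen main effect, 1 for the interaction, and 0 for nitrogen (20) and warming (63); cmr1 turned to -0.12 and Cyanide_hydratase_Fungi to -0.035 with both treatments, and cmr1 to -0.15 for the nitrogen main effect. A replicate block gave 13 families for both treatments, 2 families and 40 probes for the warming main effect, 8.81% of composition for the interaction (permutation p = 0.0452) and 5159 detected probes for both treatments (exact permutation p = 0.125, the smallest that swaps within 4 numbers allow), called 1 panel family, lower, for the nitrogen main effect, and ended the calls of sulfate_transporter with both treatments (0.59) and CsoS1_CcmK for the nitrogen main effect (-0.14). Whether the numbers pair samples stays unclear: after group means were removed, samples with the same number had a mean correlation of 0.0353 (8 of 24 pairs over 0.1) and those with different numbers -0.0111 (6 of 72), and 7 of 16 were closest to their own number. Fitting only the groups compared gave 3 families for nitrogen, and ended the calls of csy1 (0.28) and GAPDH_Parabasalia (-0.23) with both treatments at the same sizes; fewer samples then set the spread. A trended and robust limma fit called 0 families for the warming main effect (68 at an unadjusted p under 0.05) and the interaction (67). Under the common floor 7 families were called for both treatments, 9 for the nitrogen main effect, 1 for the interaction, and 0 for nitrogen (33), warming (69) and its main effect (63). With at least 5 detected probes 5 were called for both treatments, 7 for the nitrogen main effect, and 0 for nitrogen (22), warming (27), its main effect (34) and the interaction (21). Without the brightest probe of each family, which left 734 families, 0 were called in limma for nitrogen (54 at an unadjusted p under 0.05), 3 for warming, 18 for both treatments, 21 for the nitrogen and 4 for the warming main effect, and 3 for the interaction. For the nitrogen main effect CsoS1_CcmK turned to 0.012 and GAPDH_Parabasalia went to -0.099 and was not called.

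For probes, taking undetected values at the lowest value of the sample gave 45 calls for nitrogen, 105 for warming, 789 for both, 171 for the nitrogen and 594 for the warming main effect, and 67 for the interaction. Only probes listed in all 16 samples gave 4 for the interaction. Removing the intensity trend gave 360 for both treatments and 34 for the warming main effect. The interaction in composition took 9.50% on relative abundance (permutation p = 0.0275), 10.4% with Jaccard dissimilarity (permutation p = 0.0072), 9.26% with Hellinger distance (permutation p = 0.0032) and 9.96% with Jaccard above the common floor (permutation p = 0.0134), and warming took 8.23% over probes in at least 4 samples (exact permutation p = 0.069) and 8.58% above the common floor (exact permutation p = 0.0531). Above the 10th percentile the differences in detected probes were 1040.5 for warming and -233.5 for the interaction, both turned, 1406 for both treatments and 482 for the nitrogen main effect; above the common floor both treatments had 2962.5 more (exact permutation p = 0.0857).

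With each sample left out in turn, the families called ranged from 1 to 8 for nitrogen, 1 to 4 for warming, 11 to 31 for both treatments, 23 to 41 for the nitrogen main effect, 1 to 7 for the warming main effect and 2 to 6 for the interaction. The probes ranged from 0 to 1 for warming, 31 to 506 for both, 0 to 3 for the nitrogen main effect (1 without control replicate 2 or warming replicate 1, 3 without nitrogen plus warming replicate 1, 2 without replicate 3), 12 to 163 for the warming main effect and 0 to 5 for the interaction (1 without control replicate 3, 5 without nitrogen plus warming replicate 4). The lineage groups of the nitrogen main effect ranged from 1 to 2, the latter without warming replicate 2. Composition ranged from 15.5% to 19.4% for nitrogen and from 7.90% to 9.66% for warming, with an exact permutation p of 0.0563 to 0.135 without control replicates 1 and 3, warming replicates 1 and 2, nitrogen replicates 2 to 4, and nitrogen plus warming replicates 1 and 2. The interaction ranged from 8.22% to 10.3%, with a permutation p of 0.0463 (9.82%) without nitrogen plus warming replicate 3 and 0.0348 (10.3%) without replicate 4. The difference in detected probes was 2865 to 4729 for nitrogen (4729 without nitrogen replicate 4, exact permutation p = 0.0286) and 4208 to 5982 for both treatments, where leaving out any control gives an exact permutation p of 0.0571, for values of 5301, 5696, 5430 and 4208. It was -299.9 to 587 for the warming main effect, turned without control replicate 4 (-299.9), warming replicate 2 (-56.0), nitrogen replicate 4 (-281.5) and nitrogen plus warming replicate 1 (-136.5), and 1422.5 to 3286 for the interaction (3286 without control replicate 4, permutation p = 0.0389).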

Other observations

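Of the tests here, the enrichment of gene categories among risen probes, that of domains among probes lost with warming, and the camera tests of the table's own groupings were chosen only after results had been seen, and that of domains among gained probes before.

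Some single probes changed with both treatments in families that did not pass. Of 223 probes tested for dsra, dissimilatory sulfite reductase, 4 rose, by 0.41 to 1.48, among them a probe from Desulfovibrio vulgaris (0.54); sulfur genes were 3.75% of the risen and 2.72% of the tested probes, and the category did not pass (Fisher's exact test, adjusted p = 0.708). Glutamine synthetase, glnA, which assimilates ammonium, had, of 278 tested, 4 probes higher and 1, from Rubrobacter xylanophilus, lower by a log2 difference of -1.69. The magnesium and cobalt transporter corA had 5 of 462 probes higher and 1 lower, and the multidrug efflux genes Mex had 4 of 1235 higher. Over all probes 184 of 39102 passed, a larger share than that of Mex. For the warming main effect, MFS_antibiotic had 4 of 3038 probes higher and ABC_antibiotic_transporter 3 of 304. Over all probes 68 of 39102 passed, a larger share than that of MFS_antibiotic.

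Among 71 subcategories of the table searched per contrast, genes for the invasion of host cells, 10 families, had a median of -0.12 with warming, 7 of 10 families lower (camera adjusted p = 1.29e-05), and of -0.08 for the warming main effect, 8 of 10 lower (adjusted p = 3.17e-05). With an estimated correlation they did not pass (adjusted p 0.142 and 0.18). Without the family cia, blank in warmed samples, the medians were -0.08 and -0.07 over 9 families, 6 and 7 of them lower. Some probes of the named families were listed in at least 3 of 4 samples with both treatments and in no control. For cmr1 they included those from Thermus aquaticus, Meiothermus ruber and Allochromatium vinosum. For Cyanide_hydratase_Fungi they came from Fusarium lateritium, Nectria haematococca and Arthroderma gypseum. A probe names the source of its sequence, and related sequences may bind to it; under the common floor the cmr1 difference was 0.54.

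A candidate explanation of the probes that rose with both treatments was that they belong to a certain function. Metal homeostasis made up 30.0% of the 160 risen probes and 26.1% of those tested, and no category passed (Fisher's exact test, smallest adjusted p = 0.492). A candidate explanation of the 1208 probes detected in all samples with both treatments and in no control was that they belong to a certain domain. Bacteria made up 89.2% of them against 89.0% of the probes absent from all controls, and Fungi 5.88% against 5.45% (Fisher's exact test, smallest adjusted p = 0.824). Of these 1208 probes, 229 were also listed in all 4 nitrogen samples and 781 in no warmed sample, and their median intensity was 289.7, against 637.5 for all values listed in those samples. Of the probes lost with warming, 87.3% were bacterial against 92.0% of the background, which did not pass (Fisher's exact test, smallest adjusted p = 0.102).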
